A study of Mus musculus with 10 samples.

How the data were processed

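Total RNA was extracted from IM2 myotubes with RNA Bee, amplified with the Illumina TotalPrep kit and labelled with biotin, per the labels' protocols. The deposited data are a raw table of the 2 WTA and 3 WTD arrays, a raw table of the 2 WTA and 3 D7E arrays, and the authors' normalized values of all columns. The raw tables hold, per the file headers, a signal and a detection p-value for each of 45281 probes and each array. The signals are intensities on a linear scale that the authors deposited without normalization, and the detection p-values deposited beside them are those of the scanner software, whose version is not given in the sources used here. The authors' normalized values are log2 intensities per their range and per their match to the raw signals, with the same median of 6.45 in every column. They are quantile normalized and not centred per gene, and no direction is open because they are levels, not ratios. Arrays were assigned to WTA, WTD and D7E from the sample titles. The series text speaks of triplicates, and a WTA replicate 3 was not analysed here. The WTA signals of both raw tables were identical in 100% of values, so the 2 arrays were counted once and averaging the WTA columns of both tables changes nothing.

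The probe order of the WTD table was restored before use. As deposited, the WTD signals had rank correlations with the WTA arrays between -0.00787 and 0.0025, while the D7E signals had 0.760 to 0.780. The normalized values of the WTA arrays in the WTD set, set beside those in the D7E set, had rank correlations of -0.000697 and -0.00448. The pair of WTA ranks was unique for all 45281 probes and matched every probe of one order to one of the other, with 0 probes keeping their place and 0 matching after the ranks of one array were shuffled. After restoring, the authors' WTA values of both sets differed by 0, which the matching by WTA ranks fixes for quantile-normalized values. The WTD signals, which took no part in the matching, then had rank correlations of 0.725 to 0.789 with WTA. Fold changes of pairs of probes of one gene, not used for the matching, had a correlation of 0.547 with the restored order and 0.222 as deposited (3419 genes), against 0.504 for D7E (3383 genes). All WTD values rest on this step.

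The deposited detection p-values of WTD replicates 1 and 3 did not match the signals of those arrays, with a strongest rank correlation with any array of -0.735 and -0.711, where the other 6 arrays had -0.987 to -0.996 with their own signals. For these 2 arrays detection p-values were estimated from the signals of 23132 probes that were background on the other arrays, which departs from the design written before the data were examined. On the 6 other arrays the same estimate gave the same call as the deposited p-value for 97.3% to 98.8% of probes. All differences went one way: the estimate called more probes detected on each array, such as 14782 against 13653 on WTD replicate 2.

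Signals were background-corrected and quantile-normalized with neqc of limma 3.58.1 in R 4.3.3 (detection p-values in place of control probes, offset 16), within each raw table for the comparisons against WTA and over all 8 arrays for D7E against WTD. A probe was kept when its detection p was under 0.05 on at least 2 arrays. Each probe was tested two-sided with lmFit and eBayes, without covariates, and Benjamini-Hochberg adjusted p under 0.05 was the threshold. A probe not above background on any array of a group has only a bound there: the fold is the bright group's mean over the dim group's mean of, per array, the higher of the lowest detected level and the probe's own level. Levels compared across groups in the text come from the joint normalization for Pabpn1, the plot of levels and the values of single arrays in the closing section, and from the comparison's own normalization elsewhere. Gene symbols came from the platform annotation, with 34885 probes naming 1 symbol, 18 several and 10378 none. Of 815 list entries 813 matched a symbol and 745 were on the array. No genome build is named, so no coordinates are given. No header gives a slide or date, so batches were not tested.

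The 23 lists covered sarcomere, excitation-contraction coupling, myogenic regulators, embryonic and fibre type genes, proliferation, proteasome, protein breakdown, chaperones, unfolded protein response, poly(A) processing, splicing, oxidative phosphorylation, glycolysis, ribosomal proteins, interferon response, p53 targets and markers of other cell types. They were tested with camera (correlation 0.01, two-sided, adjusted over the 23 lists, 1 probe per gene, the brightest), again with an estimated correlation, and with fry. Named genes followed a rule fixed before the data were examined: Pabpn1, the 12 largest rises and falls past the threshold whose arrays did not overlap between groups, the 4 members with the smallest p of each list past its threshold, fewer where fewer passed, and Acta1, Myh3, Myog, Ckm, Des, Mki67, Fbxo32, Trim63 and Col1a1. The rises and falls were taken over genes with a symbol other than a clone name, each read on its brightest probe past the threshold. Unchanged groups against the same WTA arrays were simulated 100 times, and 20 times with calls counted.

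The steps were tested on simulated data with 200 changed probes, 50 at each of log2 0.5, 1, 1.5 and 2. In WTD against WTA 0, 40, 78 and 82% of them were recovered at these sizes with 6 false calls among 17071 probes. In D7E against WTA the shares were 0, 30, 78 and 90% with 1 false call among 16802, and in D7E against WTD 10, 66, 92 and 96% with 3 among 18815. The restoring step returned 45281 of 45281 shuffled probes to their place. Alternatives covered background correction, normalization, the authors' values, the filter on dim probes, the moderation of variances, a replicate block (the replicate number as a fixed effect), the arrays fitted together, thresholds, the list test and leaving out each array, where a lone WTA array is assumed to vary like the other groups. Version 1.5.0 of statmod was loaded with limma.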

Results

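Gene expression was measured on Illumina mouse bead arrays in myotubes of the IM2 mouse muscle cell line, made by keeping confluent myoblasts under fusion conditions for 4 days. The cultures expressed FLAG-tagged PABPN1, the nuclear poly(A)-binding protein whose alanine-expanded forms cause oculopharyngeal muscular dystrophy (OPMD). The labels name 3 groups. WTA arrays came from cultures with wild type PABPN1-FLAG, WTD arrays from cultures with wild type PABPN1-FLAG at a low level, and D7E arrays from cultures with mutant PABPN1-FLAG at a level the labels call similar to WTA. There were 2 WTA arrays, which stand in both raw tables with identical values and were counted once, 3 WTD arrays and 3 D7E arrays. The labels do not say whether replicates were separate cultures, so p-values measure the spread between these arrays, which may be technical. Each array held 45281 probes, of which 13653 to 17565 were detected at a detection p under 0.05. The counts of WTD replicates 1 and 3, 16241 and 17565, rest on the estimated p-values, which call more probes than deposited ones. The 95th percentile of the signal lay 3.20 to 8.37 times above the median, lowest in WTD replicate 2 and highest in WTD replicate 3. The number of arrays limits the precision.

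Pabpn1, the gene the design manipulates, had 1 probe, and whether that probe reads the introduced transcript is not given in the sources used here. Its normalized log2 intensity was 9.10 ± 0.04 (SD, n = 2) in WTA, 10.01 ± 0.22 (SD, n = 3) in WTD and 9.66 ± 0.73 (SD, n = 3) in D7E. The probe was higher in WTD than in WTA by log2 0.90 ± 0.19 (SE; limma adjusted p = 0.0423), although the labels give WTD as the low-level group. In D7E the 3 arrays read 9.05, 9.47 and 10.47, and the group differed from WTA by 0.57 ± 0.33 (SE; adjusted p = 0.462) and from WTD by -0.35 ± 0.28 (SE; adjusted p = 0.794), both within the spread between arrays. Without D7E replicate 3 these differences were 0.157 and -0.745, and without D7E replicate 1 they were 0.871 and -0.039. The WTD over WTA call for Pabpn1 was lost without WTA replicate 1 or 2 or WTD replicate 1 or 2 (log2 0.82 to 0.93, adjusted p = 0.166 to 0.276) and with arrays centred on their medians (0.67, adjusted p = 1), a centring that turned the D7E over WTD difference to 0.43 (adjusted p = 0.569).

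**Figure D1:**
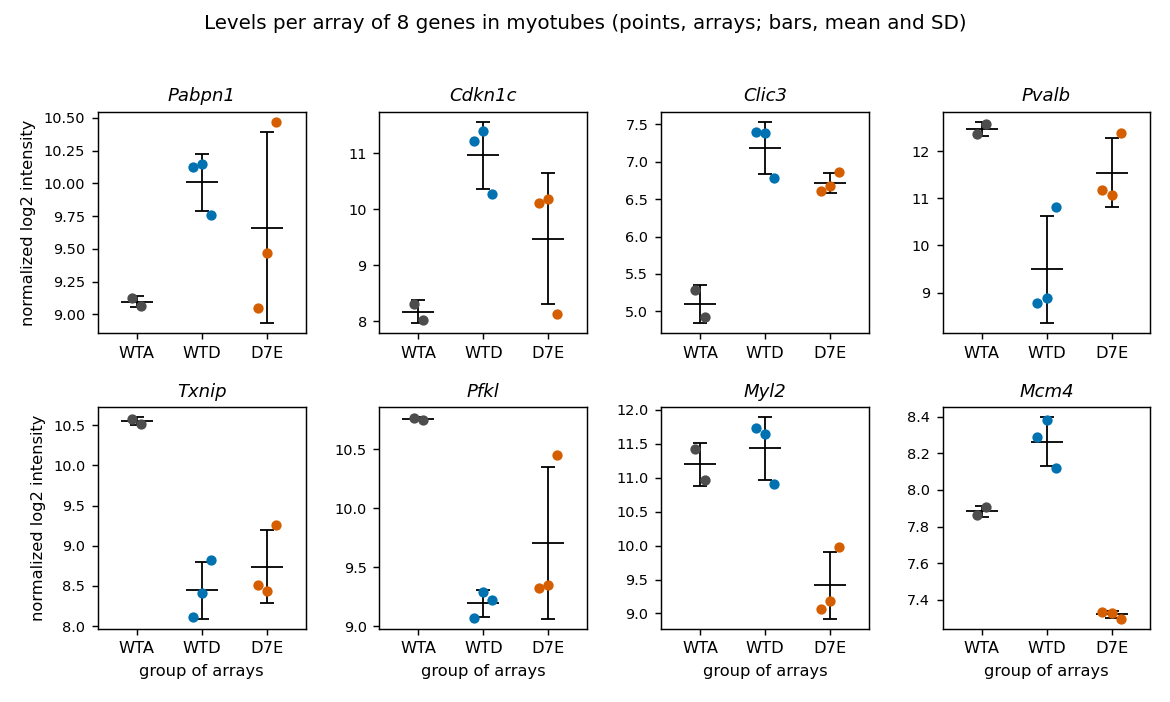
Normalized log2 intensity of 8 named genes on each array, with points for arrays and bars for the mean and SD of WTA (n = 2), WTD (n = 3) and D7E (n = 3); the y axes differ between panels and do not start at 0. Pabpn1 in D7E spans 9.05 to 10.47, Cdkn1c, Clic3, Pvalb, Txnip and Pfkl separate WTD from WTA, and Myl2 and Mcm4 separate D7E from WTD.

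The comparison of WTD with WTA asks what differs between myotubes with a low and a higher level of wild type PABPN1-FLAG. Changes are ranked here over genes with a symbol other than a clone name, each read on its brightest called probe. Over all called probes the largest change was log2 3.76 in absolute size. Of the ranked genes Cdkn1c, an inhibitor of cyclin-dependent kinases, had the largest rise in WTD, at log2 2.77 ± 0.29 (SE; 6.83-fold, adjusted p = 0.00272), from 7.92 ± 0.20 (SD, n = 2) in WTA to 10.69 ± 0.60 (SD, n = 3). Clic3, a chloride intracellular channel protein, rose by 1.97 ± 0.22 (adjusted p = 0.00281), and the potassium channel gene Kcnc4 and the signalling ligand Wnt10a both rose by 1.87 (adjusted p = 0.00805 and 0.0118). The other large rises were those of Lrrc26 (1.81), Ctsw (1.76), Pacsin1 (1.69), prostacyclin synthase Ptgis (1.57), Spink4 (1.54), Tac4 (1.52), the membrane dipeptidase Dpep1 (1.5) and the growth factor binding protein Igfbp2 (1.49). Wnt10a, Tac4 and Dpep1 were above background on 1 of the 2 WTA arrays. The largest fall of the ranked genes was that of Pvalb, the calcium buffer parvalbumin of fast fibres, at -2.96 ± 0.47 (SE; adjusted p = 0.0119), from 12.18 ± 0.16 (SD, n = 2) to 9.22 ± 1.13 (SD, n = 3).

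Also lower in WTD than in WTA were Lmcd1 at -2.09 ± 0.19, Txnip, an inhibitor of thioredoxin and of glucose uptake, at -2.08 ± 0.22, and the tight junction gene Cldn2 at -2.07 ± 0.18 (SE; adjusted p = 0.00109, 0.00272 and 0.00109). Falls followed for Thbs2, a matrix protein, at -1.84, Nrn1 at -1.75, the pyruvate dehydrogenase kinase Pdk1 at -1.69, the protease gene Htra3 at -1.62, Mybpc2, the fast isoform of myosin-binding protein C, at -1.59, the prolyl hydroxylase Egln3 at -1.58, Ptn at -1.55 and the phosphofructokinase Pfkl at -1.54, with adjusted p between 0.00281 and 0.0244. Ptn read -0.994 without WTA replicate 2, where its call was lost. Pdk1 was above background on 2 of the 3 WTD arrays. No other probe of these genes pointed the opposite way. Sizes depend on the background correction: with quantile normalization alone and in the authors' values, both without it, 15 of the 30 called named genes had sizes over 1.5 times smaller than given here, among them Clic3 (0.977 and 1.09), Kcnc4 (0.807 and 0.906) and Wnt10a (0.763 and 0.856), while Cdkn1c (2.47 and 2.55) and Pvalb (-2.79 and -2.83) stayed the largest of those named. Pvalb, Kcnc4 and Wnt10a lost their calls in both. Of the genes named whatever their values, none passed the threshold: Col1a1 read -0.74 (adjusted p = 0.081), Trim63 -0.43, Ckm -0.42, Acta1 -0.12, Fbxo32 0.13, Des 0.13 and Myog 0.27 (adjusted p = 0.367 to 0.86). Myh3 and Mki67 were not measured.

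In all, 225 of 17071 probes differed between WTD and WTA at an adjusted p under 0.05, 129 higher and 96 lower in WTD. They covered 168 genes with a symbol, 99 higher and 69 lower, and the median absolute log2 change was 1.12. At an unadjusted p under 0.05 there were 2152 probes, against 854 expected without any difference. The count rests on single arrays, with 24 probes without WTA replicate 1, 63 without WTA replicate 2, 34 without WTD replicate 1, 61 without WTD replicate 2 and 326 without WTD replicate 3, and it fell to 0 when arrays were centred on their medians or when no filter on dim probes was used. With that centring 138 probes had an unadjusted p under 0.05, and without the filter 3722 of 45281.

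Of 23 gene lists fixed before the data were examined, 5 shifted in WTD against WTA. Genes of glycolysis and glycogen fell together, with a mean log2 change of -0.49 over 21 measured genes (camera adjusted p = 1.32e-07, and adjusted p = 0.201 with an estimated correlation). Of these 17 had a value below 0, 6 fell past the threshold over all probes and 8 adjusted over the list alone. The 4 with the smallest p were Pfkl at -1.54, the glucose transporter Slc2a1 at -1.34 ± 0.18, phosphoglycerate kinase Pgk1 at -0.999 ± 0.18 and Pgam1 at -1.10 ± 0.21 (SE; adjusted p = 0.00281 to 0.0295). Fast fibre genes fell (16 measured, mean -0.40, adjusted p = 0.0135, and adjusted p = 0.286 with an estimated correlation) through a few members, with 2 past the threshold over all probes, Pvalb and Mybpc2, and 3 adjusted over the list alone. Actn3 read -0.60 (adjusted p = 0.185), and the median of the list was only -0.05. Sarcomere genes fell (47 measured, mean -0.20, adjusted p = 0.00655, and adjusted p = 0.435 with an estimated correlation), with 2 past the threshold over all probes, Mybpc2 and Tmod4, a capping protein of thin filaments that fell by 1.34 ± 0.27 (SE). Adjusted over the list alone, 7 sarcomere genes were lower and 1 higher. Ldb3 at -0.93 (-0.573 without WTA replicate 1) and Nrap at -0.67 did not pass over all probes (adjusted p = 0.0806 and 0.124).

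Cytosolic ribosomal protein genes rose together in WTD against WTA (40 measured, 33 with a value above 0, mean 0.26, camera adjusted p = 2.62e-05, and adjusted p = 0.201 with an estimated correlation) without any single member passing, over all probes or adjusted over the list alone. Genes of oxidative phosphorylation rose (60 measured, mean 0.17, adjusted p = 0.00655, and adjusted p = 0.201 with an estimated correlation), 1 of them past the threshold over all probes and 7 adjusted over the list alone. That 1 was Ndufa3, a subunit of complex I, at 1.10 ± 0.22 (SE; adjusted p = 0.0316). Cox6b1 read 0.78, Ndufc2 0.76 with another probe in the opposite direction, and Cox6c 0.74 (adjusted p = 0.055, 0.0772 and 0.088). With a correlation estimated from the data none of the 5 lists passed. That estimate was -0.00712 for oxidative phosphorylation and -0.0233 for fast fibre genes, below the fixed 0.01. A higher correlation is therefore not what cost these lists their calls. It was 0.0445 for sarcomere, 0.0177 for glycolysis and 0.0152 for ribosomal protein genes. In simulated data a shifted list went from a camera adjusted p of 1.64e-32 to 0.0169 with the estimate, so this form of the test detects less. Without WTA replicate 1 the fast fibre and sarcomere calls were lost, without WTD replicate 3 the sarcomere call, and with median centring the call for oxidative phosphorylation.

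**Figure D2:**
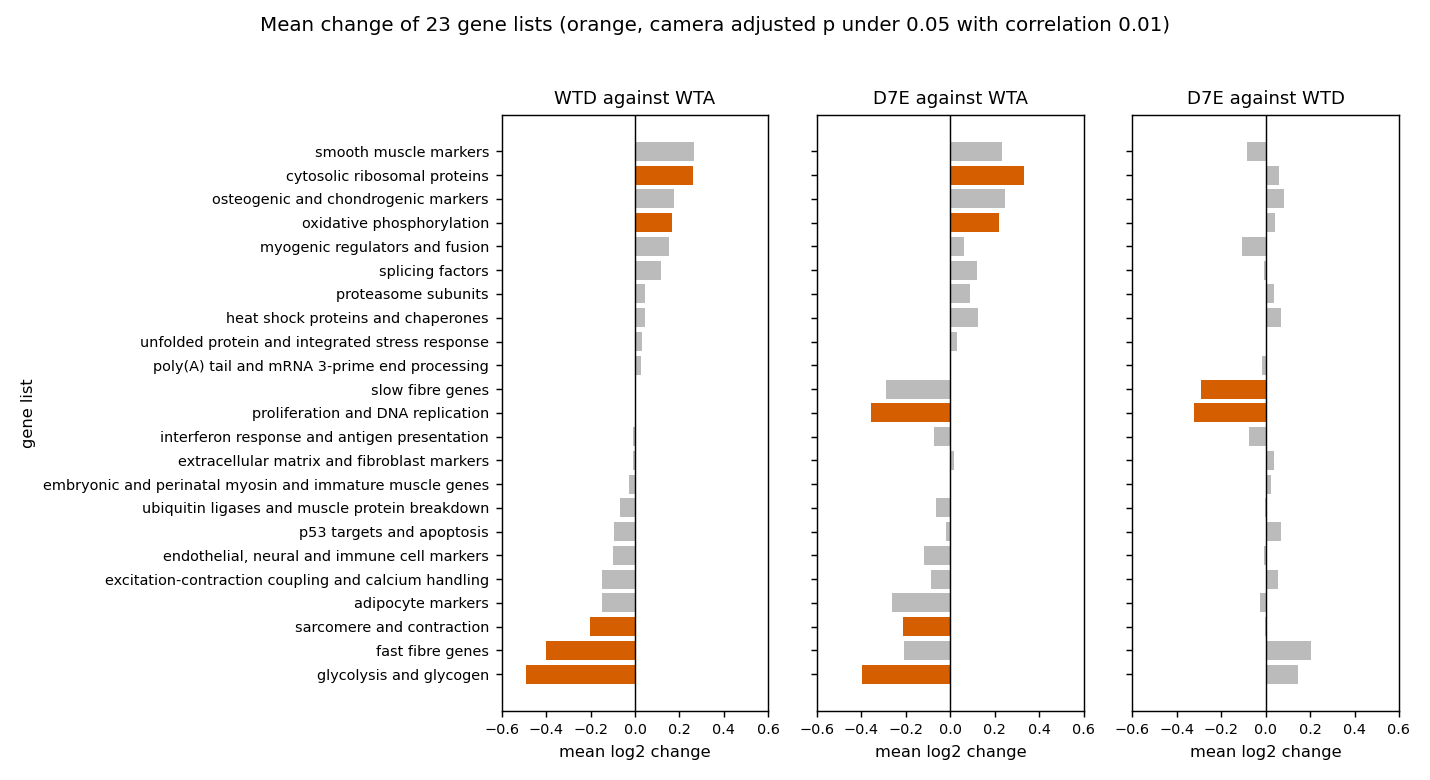
Mean log2 change of the measured members of 23 gene lists (y axis) in the 3 comparisons (panels, x axis in log2 units); orange bars have a camera adjusted p under 0.05 at a correlation of 0.01, and none of them passed with an estimated correlation. Against WTA, glycolysis and sarcomere lists are below 0 and ribosomal protein and oxidative phosphorylation lists above 0 in both WTD and D7E. The proliferation list is at -0.36 in D7E against WTA and -0.32 in D7E against WTD. With arrays centred on their medians the slow fibre mean of D7E against WTD turns to 0.36, while the median of all tested probes shifts by 0.401.

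The comparison of D7E with WTA sets mutant against wild type PABPN1-FLAG at levels that the labels call similar. On the main normalization Dpep1 had the largest rise in D7E, by log2 1.78 ± 0.22 (SE; 3.43-fold, adjusted p = 0.0162), from 4.87 ± 0.51 (SD, n = 2) to 6.65 ± 0.13 (SD, n = 3). Clic3 rose by 1.72 ± 0.19, the chemokine gene Cxcl14 by 1.47 ± 0.21, Pacsin1 by 1.43 ± 0.21, the smooth muscle marker Tagln by 1.38 ± 0.19 and the gap junction gene Gja5 by 1.33 ± 0.21 (SE; adjusted p = 0.0124 to 0.032). One probe of Ryr1, the calcium release channel of the sarcoplasmic reticulum, rose by 1.39 while its 4 other probes pointed the opposite way, and one of Appl1 rose by 1.30 with 1 of 2 other probes opposite, so neither gene has a settled direction. Rpl38 (1.25 on this probe), the phosphatase gene Dusp2 (1.21), the mitochondrial RNA-binding protein gene Slirp (1.19) and Bola2 (1.16) completed the 12 rises named by the rule. Some called probes without a symbol or with a clone name rose more than some of these 12, such as ILMN_2497616 by 1.656 and 2310002L09Rik by 1.409. Dpep1, Ryr1 and Appl1 were above background on 1 of the 2 WTA arrays.

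Txnip fell most in D7E against WTA, at -1.82 ± 0.24 (SE; adjusted p = 0.018), followed by Myl2, the regulatory myosin light chain of slow fibres and ventricle, at -1.79 ± 0.27 (SE; adjusted p = 0.0221), from 11.42 ± 0.31 (SD, n = 2) to 9.63 ± 0.50 (SD, n = 3). Other falls named by the rule were those of Pdk1 at -1.63, Mgarp at -1.60, the nuclear pore gene Nup210 at -1.60, Cldn2 at -1.58, the lipoprotein receptor Vldlr at -1.52, Arrdc4, an arrestin-family relative of Txnip, at -1.38, Cdsn at -1.31, the class II histocompatibility gene H2-Ab1 at -1.27 and the small GTPase Rrad at -1.26 (adjusted p = 0.0124 to 0.0496). Lmcd1 (-1.222 and -1.357) and Ckmt2 (-1.161 and -1.304) were also called lower but not named, since each gene stands for its brightest called probe. The phosphatase gene Dupd1 was not above background on any D7E array and at least 2.65-fold lower there on the background-corrected scale (adjusted p = 0.0124), and H2-Ab1 was above background on 2 of the 3. Without background correction, by quantile normalization alone and in the authors' values, 12 of the 24 called named genes had sizes over 1.5 times smaller, among them Dpep1 (0.764 and 0.713) and Dupd1 (-0.547 and -0.504), and of those named Pacsin1 (1.31 in both) then rose most and Myl2 fell most (-1.69 and -1.68). In both, 13 of the 24 lost their call, Myl2 among them. None of the genes named whatever their values passed: Ckm read -0.58, Trim63 -0.45, Col1a1 -0.34, Des -0.17, Acta1 -0.10, Fbxo32 0.17 and Myog 0.47 (adjusted p = 0.182 to 0.848). Leaving out one array moved Col1a1 from -0.444 to -0.193, Des from -0.316 to -0.024, Fbxo32 from 0.0367 to 0.313 and Acta1 from -0.238 to 0.0386. With arrays centred on the medians of all 45281 probes Col1a1, Des, Acta1 and Ckm turned to values above 0, while the median of the tested probes shifted by 0.307. With that shift taken out they read -0.0725, 0.119, 0.16 and -0.297, in the same order.

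In D7E against WTA 74 of 16802 probes passed, 41 higher and 33 lower in D7E. They covered 49 genes with a symbol, 27 higher and 22 lower. At an unadjusted p under 0.05 there were 2539 probes, with 840 expected. Setting D7E replicates 1 and 2 against D7E replicate 3 and both WTA arrays called 106 probes, more than the real groups. No probe passed without WTA replicate 1, D7E replicate 1 or D7E replicate 2 (2130, 1628 and 1636 at an unadjusted p under 0.05), 257 passed without D7E replicate 3 and 70 without WTA replicate 2. None passed without a filter on dim probes (4393 at an unadjusted p under 0.05), while centring on array medians called 1648, of which 1616 were higher.

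The list shifts of D7E against WTA included a fall of proliferation and DNA replication genes (28 measured, 24 with a value below 0, mean -0.36, camera adjusted p = 1.58e-06, and adjusted p = 0.174 with an estimated correlation). None of them passed over all probes and 12 did adjusted over the list alone. The smallest p values belonged to Mcm5, a subunit of the replicative helicase, at -0.82 ± 0.17, the centromere histone Cenpa at -1.10 ± 0.23, Top2a and Birc5 at -0.67 ± 0.16 (SE; adjusted p = 0.0675 to 0.0955). Top2a was not above background on any D7E array and at least 1.51-fold lower there on the background-corrected scale. With quantile normalization alone and in the authors' values the proliferation list stayed past its threshold, but its median went from -0.402 to -0.139 and -0.128, Top2a read -0.223 and -0.204, Birc5 -0.224 and -0.204 and Mcm5 -0.362 and -0.336. The glycolysis median went from -0.529 to -0.216 and -0.197. Glycolysis and glycogen genes fell (21 measured, mean -0.40, adjusted p = 2.94e-05, and adjusted p = 0.469 with an estimated correlation), 12 of them adjusted over the list alone and none over all probes, with Pygm, muscle glycogen phosphorylase, at -0.83, Pkm at -0.61, Pfkl at -1.06 and lactate dehydrogenase Ldha at -0.53 (adjusted p = 0.0641 to 0.174). Sarcomere genes fell (49 measured, mean -0.21, adjusted p = 0.00376, and adjusted p = 0.469 with an estimated correlation), with Myl2 the only member past the threshold over all probes and 7 adjusted over the list alone. Mybpc2 read -1.15, Nrap -0.78 and Tmod1 -0.75 (adjusted p = 0.071 to 0.0773).

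Ribosomal protein genes rose in D7E against WTA (39 measured, 36 with a value above 0, mean 0.33, camera adjusted p = 3.44e-08, and adjusted p = 0.174 with an estimated correlation), 2 of them adjusted over the list alone, Rps21 at 0.84 and Rpl30 at 0.83, and none over all probes (adjusted p = 0.0682 and 0.0766). In this list each gene stands for its brightest probe, which for Rpl38 was not the probe named among the largest rises. Oxidative phosphorylation genes rose (60 measured, mean 0.22, adjusted p = 5.89e-05, and adjusted p = 0.174 with an estimated correlation), 10 adjusted over the list alone and none over all probes, with Cox7a2 at 0.78, Uqcrq at 0.71, Cox6c at 0.85 and Ndufb4 at 0.69 (adjusted p = 0.0691 to 0.0964). With median centring the sarcomere call was lost and Pkm and Ldha turned to 0.02 and 0.06, against a shift of 0.31 in the median of all probes. The estimated correlation was -0.0142 for proliferation genes, below the fixed 0.01, and 0.011 to 0.196 for the other called lists. A shifted list in simulated data went from a camera adjusted p of 2.82e-36 to 0.0143 with the estimate.

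The comparison of D7E with WTD sets mutant against low-level wild type PABPN1-FLAG, and it is also the test of whether both groups differ from WTA by different amounts. Lower in D7E were 6 of 18815 probes, and none was higher. Myl2 fell by 2.02 ± 0.26 (SE; 4.06-fold, adjusted p = 0.0316), from 11.43 ± 0.46 (SD, n = 3) in WTD to 9.41 ± 0.49 (SD, n = 3). The homeobox gene Irx2 and Taf9b, a relative of a TFIID subunit, were not above background on any D7E array and at least 2.94-fold and 2.65-fold lower there on the background-corrected scale (adjusted p = 0.0197 and 0.0381). With quantile normalization alone and in the authors' values Irx2 read -0.665 and -0.668, Taf9b -0.639 and -0.641 and Kcnc4 -0.747 and -0.76. In both, Irx2, Taf9b, Kcnc4, Myl2 and Tceal5 lost their calls. Also lower in D7E were Tceal5 at -1.65 ± 0.22, Kcnc4 at -1.56 ± 0.22 and the helicase subunit Mcm4 at -0.94 ± 0.14 (SE; adjusted p = 0.0316, 0.04 and 0.0443). Mcm4 read 7.32 ± 0.02 (SD, n = 3) in D7E, 8.26 ± 0.13 (SD, n = 3) in WTD and 7.88 ± 0.03 (SD, n = 2) in WTA. Col1a1 read 0.40, Des -0.29, Ckm -0.17, Acta1 0.00, Fbxo32 0.04, Trim63 0.03 and Myog 0.20, none past the threshold (adjusted p = 0.549 to 0.996).

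At an unadjusted p under 0.05 there were 1524 probes in D7E against WTD, with 941 expected. The count was 80 without WTD replicate 3, 2 without WTA replicate 2, 1 without WTA replicate 1 or without D7E replicate 3, and 0 without any one of WTD replicates 1 and 2 and D7E replicates 1 and 2. It was also 0 with arrays centred on their medians. Of the lists, proliferation and DNA replication genes fell in D7E against WTD (29 measured, 22 with a value below 0, mean -0.32, camera adjusted p = 4.94e-07, and adjusted p = 0.188 with an estimated correlation), Mcm4 past the threshold over all probes and 10 adjusted over the list alone. The median of -0.265 became -0.0823 with quantile normalization alone and -0.0817 in the authors' values, with the call kept. Cdk1, the mitotic kinase, read -0.81 ± 0.16, and the helicase subunits Mcm6 and Mcm5 read -0.96 ± 0.20 and -0.97 ± 0.22 (SE; adjusted p = 0.156 to 0.231). Slow fibre genes fell (13 measured, mean -0.29, adjusted p = 0.0309, and adjusted p = 0.517 with an estimated correlation), with Myl2 past the threshold over all probes and 2 adjusted over the list alone, the other being tropomyosin Tpm3 at -0.61 ± 0.15 (SE; adjusted p = 0.28). The slow fibre call was lost without WTD replicate 1, WTD replicate 2 or D7E replicate 3, and its mean turned to 0.36 with median centring. That centring, which shifted the median of all probes by 0.40, also called sarcomere, fast fibre, oxidative phosphorylation, glycolysis and ribosomal protein genes as rises in D7E against WTD (adjusted p = 0.000155, 0.000108, 5.31e-07, 0.019 and 7.09e-07).

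Changes against WTA were set side by side for WTD and D7E, which share the 2 WTA arrays. Of 15811 probes tested in both comparisons, 24 were higher in both, covering 18 genes such as Clic3, Dpep1, Pacsin1, Gja5, Tagln and Cxcl14. Lower in both were 25 probes of 16 genes such as Txnip, Lmcd1, Cldn2, Pdk1, Mgarp and Vldlr. Independent lists would share 0.321 and 0.200 probes, an expectation that leaves out the shared WTA arrays. Simulated unchanged groups with 2 shared WTA arrays had 0 probes called in both in each of 20 sets. Independent noise leaves few probes to be called at all, so this decides nothing. That 0 probes were called in opposite directions decides little either, since both comparisons subtract the same WTA arrays. Over 18815 probes, which are not independent replicates, the fold changes had a correlation of 0.722 and a covariance of 0.0668. Unchanged groups simulated with 2 shared WTA arrays gave a correlation of 0.60 and a covariance of 0.0291, lower by 0.0377. Each probe was drawn independently there, so deviations that many probes of a real array share are not covered. With a different WTA array for each comparison the correlation was 0.302 or 0.254. Of the 225 probes called in WTD, 3 also differed between D7E and WTD after adjustment and 84 at an unadjusted p under 0.05, and of the 74 called in D7E, 1 and 20.

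**Figure D3:**
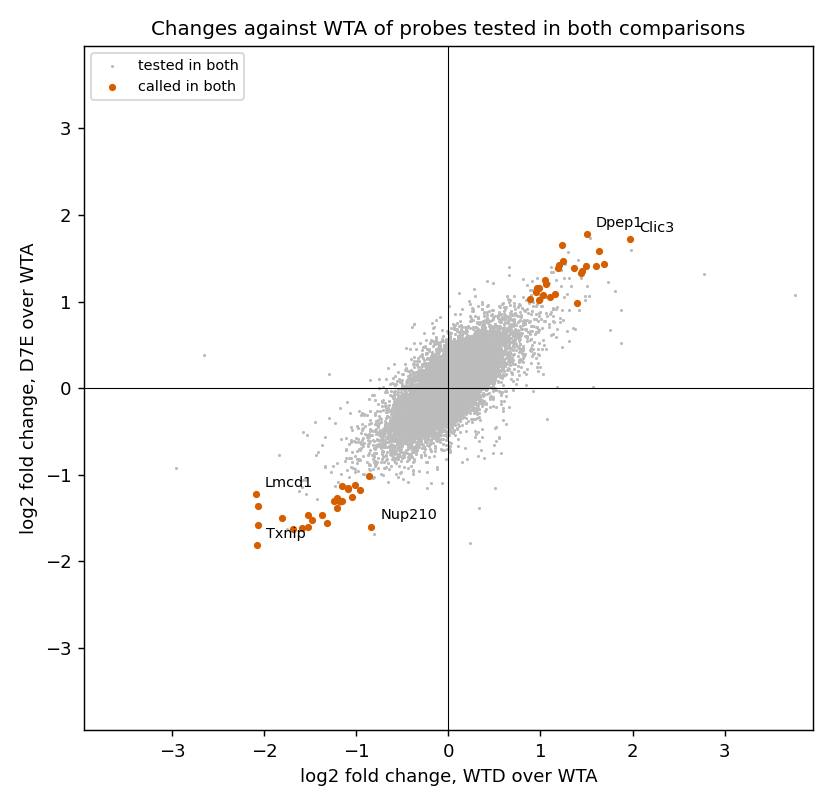
Log2 fold change of WTD over WTA (x axis) against that of D7E over WTA (y axis) for the 15811 probes tested in both comparisons, each point a probe; orange points passed the threshold in both. The 24 orange points at the upper right and 25 at the lower left all keep one direction, and both axes share the same 2 WTA arrays.

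The 16 remaining lists had no camera adjusted p under 0.05 in any comparison with the main normalization. With arrays centred on their medians, proteasome subunits, chaperones and splicing factors passed as rises in D7E against WTA (adjusted p = 0.00159, 0.00432 and 0.00526), and proteasome subunits, chaperones and embryonic muscle genes in D7E against WTD (adjusted p = 0.000712, 0.00493 and 0.00113), while endothelial, neural and immune markers passed as lower than other genes in both (adjusted p = 0.0169 and 0.00898). Without WTA replicate 2, splicing factors and matrix markers passed as rises in WTD (adjusted p = 0.00798 and 0.0348) and in D7E (adjusted p = 0.00197 and 0.00747) against WTA, and splicing factors also passed in WTD without WTD replicate 2 (adjusted p = 0.0288) and in D7E with no filter on dim probes (adjusted p = 0.0326). Without D7E replicate 2, myogenic regulators passed as a fall in D7E against WTD (adjusted p = 0.0285). Values below are mean log2 changes of WTD against WTA, D7E against WTA and D7E against WTD, in that order. The proteasome subunits, 40 of which were measured, read 0.05, 0.09 and 0.04, with no subunit past the threshold. Ubiquitin ligases and other protein breakdown genes read -0.07, -0.07 and 0.00, heat shock proteins and chaperones 0.04, 0.12 and 0.07, and unfolded protein response genes 0.03, 0.03 and 0.01. Genes of poly(A) tail and 3' end processing read 0.03, 0.00 and -0.02, with Pabpn1 in WTD against WTA the only member past the threshold. Splicing factors read 0.12, 0.12 and -0.01, interferon response genes -0.01, -0.07 and -0.07, and p53 targets and apoptosis genes -0.09, -0.02 and 0.07. Excitation-contraction coupling genes read -0.15, -0.09 and 0.05, myogenic regulators 0.15, 0.06 and -0.11, and embryonic and perinatal muscle genes -0.03, 0.00 and 0.02.

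Among markers of other cell types, extracellular matrix and fibroblast markers read -0.01, 0.02 and 0.04 in the same order, smooth muscle markers 0.27, 0.23 and -0.08, and adipocyte markers -0.15, -0.26 and -0.03. Osteogenic and chondrogenic markers, of which 3, 3 and 4 genes were measured, read 0.175, 0.25 and 0.08, and endothelial, neural and immune markers -0.10, -0.12 and -0.01. With fry in place of camera the smooth muscle markers passed as a rise in WTD against WTA (fry adjusted p = 0.0362, 8 of 9 above 0). Tagln, a smooth muscle marker, was higher in both WTD, by 1.36, and D7E, by 1.38, than in WTA. The median and the mean of a list had different signs for excitation-contraction coupling genes in WTD against WTA and in D7E against WTD, for interferon response genes in WTD against WTA (median 0.01, mean -0.01), for osteogenic markers in both comparisons against WTA, for smooth muscle markers and embryonic muscle genes in D7E against WTA, and for proliferation genes in WTD against WTA and sarcomere genes in D7E against WTD, where the means were 0.00. The test of the matrix markers in WTD against WTA pointed up while their mean and median were -0.01.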

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

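The search for an array that matches the unused detection p-values, the comparisons with stand-in arrays, those of WTD replicate 1 the reading of probes picked against 1 WTA array and the correlations with an array left out were tests chosen after the results were seen; the other tests in this part were written down before.

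WTD and D7E moved together against WTA, with 49 probes called in both and 0 in opposite directions. The covariance of the fold changes, 0.0668, lay above the highest of 100 simulated sets, 0.0304. The simulation drew each probe independently and does not cover deviations that many probes of a real array share. It therefore does not decide on the 2 shared WTA arrays alone. With a different WTA array for each comparison, where no array is shared, the correlation was 0.302 and 0.254. With array brightness as a covariate 100% of the 49 probes kept their direction and an unadjusted p under 0.05 in both comparisons. Their median absolute log2 change was 1.33 without and with the covariate in WTD, and 1.3 and 1.29 in D7E. These probes were picked on the same arrays at a stricter threshold. The values therefore show only that this covariate does not remove their differences, and brightness is not excluded. A single odd WTA array as the whole cause is argued against by the correlation with a different WTA array for each comparison, 0.302 and 0.254, and 0.166 at its lowest with any 1 of the 6 other arrays left out, where it would be 0 or below in one of both ways (that 100% of the 49 probes lay on the same side of either WTA array was fixed by how they were called and decides nothing), but a part played by 1 WTA array stays open, since of 200 probes picked in one group against 1 WTA array 64, 75.5, 94 and 94% kept their direction in the other group against the other WTA array, above the 50% of chance and for 2 choices under the 80% set for excluding it. Handling of both WTA cultures or arrays apart from the others also stays open, since 0 header lines name a slide, batch or date, so it cannot be told apart from a biological difference of WTA from both other groups, which the design names and which was not tested.

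In data no comparison used, the unused detection p column of WTD replicate 1 called 14272 probes detected and that of WTD replicate 3 called 12027, and these columns match no array analysed here (strongest rank correlation -0.735), which leaves open what they belong to. For replicate 1 an origin of its signals in a WTA culture is argued against. It showed 0.984 and 0.943 of the shift of replicates 2 and 3 from 1 WTA array, and 0.857 and 0.733 from held-out WTA arrays. The left out WTA arrays standing in for it showed 0.109 and 0.249. An origin of replicate 1 in a D7E culture is argued against by the stand-in test alone and stays open. It showed 0.808 to 0.864 of the shift of replicates 2 and 3 from 2 D7E arrays, against 0.271 to 0.326 for the stand-ins. From held-out D7E arrays it showed 0.447 to 0.521, at its lowest short of the bound for exclusion set for replicate 3. Its correlations were 0.9861, 0.9864 and 0.9829 with the D7E arrays, and 0.9846 and 0.9853 with WTD replicates 2 and 3. For replicate 3 an origin in a WTA culture stays open. A correlation written down before (0.389 and 0.0048) met its bound for that origin. The share from the held-out WTA array, 0.442 and 0.605, fell short of the bound for excluding it. In the stand-in test chosen later, replicate 3 showed 0.605 and 0.798 of the shift of replicates 1 and 2 from 1 WTA array over 200 probes. The other WTA array standing in for it showed 0.235 and 0.137. On the joint normalization replicate 3 had correlations of 0.976 and 0.9864 with WTA replicates 1 and 2, and 0.9853 and 0.9771 with WTD replicates 1 and 2. With D7E replicates 1, 2 and 3 the correlations were 0.9893, 0.9896 and 0.9838, so its highest values were with D7E replicates 1 and 2. An origin of replicate 3 in a D7E culture cannot be told apart from a WTD array that stands apart from replicates 1 and 2: the share from a held-out D7E array was 0.0905 at its lowest (0.184 and 0.139 for the others), within the bound for that origin, and the correlations were -0.0255, -0.0257 and 0.0131, but from the other 2 D7E arrays the share was 0.319 to 0.357, above the 0.114 to 0.174 of the D7E arrays standing in for it. Gpx7, an endoplasmic reticulum peroxidase chosen after its values were seen, bears on the same question, reading 4.42 and 4.39 in WTD replicates 1 and 2, near background, but 8.41 in replicate 3, with 8.88 to 9.0 on the D7E arrays and 8.48 and 8.62 on the WTA arrays; as 1 gene it does not decide between them.

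Differences of D7E and WTD in their change against WTA, tested directly in the D7E against WTD comparison, were -2.02 for Myl2, -1.64 for Tceal5, -1.56 for Kcnc4 and -0.94 for Mcm4 (log2). The fitted values of -1.75 for Irx2 and -1.68 for Taf9b are not sizes, since neither was above background on any D7E array. For these genes only the bounds given above hold. The mean difference was -0.324 for proliferation and DNA replication genes and -0.291 for slow fibre genes (camera adjusted p = 0.188 and 0.517 with an estimated correlation). With arrays centred on their medians the slow fibre mean turned to 0.361, while the median of all tested probes shifted by 0.401.

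The counts of splits given here include the real split itself. Of the 10 splits of the 5 arrays of WTD and WTA, 1 gave as many probes as the real 225, with 65 at most in another split. For D7E and WTA 2 of 10 did, the highest other split giving 106 against the real 74 when D7E replicates 1 and 2 were set against the rest, which points to a structure among the D7E arrays. For D7E and WTD 1 of 10 did, with 6 in the real split and 5 at most in another. With 10 splits a share under 0.05 cannot be reached.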

How the results depend on the processing

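Chosen after the data were seen were the alternatives on the row order, the estimated or deposited detection p-values, the array brightness, the median of detected probes and the arrays in doubt. The counts of changed probes moved with most settings, and the cause was not tested unless stated. For WTD against WTA (225) the count was 0 with median centring, with centring on the median of detected probes and with no filter on dim probes, 388 with a trended robust eBayes, 455 with brightness as a covariate, 50 at an adjusted p under 0.01 and 13655 with the WTD rows as deposited, where probes are mismatched. For D7E against WTA (74) it was 160 with normexp, 1648 (1616 higher, 32 lower) with median centring, 0 with no filter and at an adjusted p under 0.01, 39 with a detection p under 0.01 in every array, 272 with a trended robust eBayes, 130 with all arrays fitted together, 124 with estimated detection p-values, 43 with one probe per gene and 327 with brightness as a covariate. For D7E against WTD (6) it was 2 with quantile normalization alone, with normexp, with the authors' values and with only the 6 D7E and WTD arrays, 3 with the stricter detection filter, 0 with median centring, with centring on the median of detected probes, with no filter and at an adjusted p under 0.01, 19 with a trended robust eBayes, 1 with brightness as a covariate, 58 with WTD replicates 1 and 3 left out and 14716 with the rows as deposited. Leaving out one array gave 24 to 326, 0 to 257 and 0 to 80 probes, 3 to 7, 5 to 8 and 1 to 4 lists, and a correlation of fold changes from 0.637 to 0.807. WTD replicate 2 had the lowest signal over background, 3.20, and the fewest detected probes, and WTD replicate 3 the highest, 8.37; without the first the counts fell to 61 and 0 and without the second they were 326 and 80, and whether signal over background limits the calls was not tested.

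With the replicate numbers as a block the counts were 556 and 269 against WTA and 8 in D7E against WTD. Against WTA, number 3 had no WTA array, so WTD or D7E replicate 3 was fitted exactly and dropped out of the contrast. The 556 and 269 therefore do not by themselves show an effect of pairing. Leaving out replicate 3 without a block gave 326 and 257. In D7E against WTD, Myl2 and Mcm4 lost their calls with the block (adjusted p = 0.052 and 0.0846). No other named gene or list called lost its call, while myogenic regulators passed as a 6th list in WTD against WTA (rise, adjusted p = 0.0396). The deviations of same-numbered arrays had correlations of -0.278 to 0.152. Those of the 2 WTA arrays mirror each other, so these few values cannot show whether the numbers pair the arrays. The number of lists past the threshold (5, 5 and 2) was 0 in all 3 comparisons with an estimated correlation, 3 with fry for D7E against WTA and 1 for D7E against WTD, while in WTD against WTA fry kept 4 of 5, lost the sarcomere list (adjusted p = 0.161) and added smooth muscle markers as a rise (adjusted p = 0.0362), 8 (5 rises, 3 falls) and 10 (8 rises, 2 falls) with median centring for D7E against WTA and WTD, (4 in each among the 16 lists called in no comparison with the main normalization, and 4 and 8 of these with centring on detected probes), and 2 and 1 with WTD replicates 1 and 3 left out for WTD against WTA and D7E against WTD. The correlation of fold changes was 0.302 and 0.254 with a different WTA array for each comparison. Median centring shifted the median of all probes by -0.104, 0.307 and 0.401, and reversed Des and Fbxo32 in WTD against WTA (-0.00875, -0.0379), Col1a1, Des, Acta1, Ckm, Pkm and Ldha in D7E against WTA (0.235, 0.426, 0.468, 0.0106, 0.0188, 0.056), and Des, Acta1, Ckm, Pabpn1, Tpm3 and the slow fibre list in D7E against WTD (0.435, 0.773, 0.607, 0.425, 0.144, 0.361). Centring on detected probes reversed Acta1 in D7E against WTA (0.0261) and Acta1, Fbxo32 and Trim63 in D7E against WTD (0.107, -0.0511, -0.168). Leaving out WTD replicates 1 and 3 reversed Fbxo32 in WTD against WTA (-0.124) and Ckm and Myog in D7E against WTD (0.0317, -0.214). Leaving out one array took Acta1 through 0 in WTD against WTA (-0.299 to 0.0416), D7E against WTA (-0.238 to 0.0386) and D7E against WTD (-0.036 to 0.0578), and likewise Des in WTD against WTA (-0.0136 to 0.272), Fbxo32 (-0.0938 to 0.134) and Trim63 (-0.0842 to 0.148) in D7E against WTD. Without background correction (quantile alone or the authors' values) 15 of 30, 12 of 24 and 3 of 6 called named genes had sizes over 1.5 times smaller, all in the same direction. No named gene past the threshold reversed in the settings run for single genes, which were quantile normalization alone, both centrings, the authors' values, the replicate block and arrays left out. Of results for single genes by setting, 824 kept their direction and side of the threshold, 316 lost a call, 40 gained one and 30 reversed. With the authors' values 20 of 30 called named genes kept their call in WTD against WTA, 11 of 24 in D7E against WTA and 1 of 6 in D7E against WTD. Without one array 14 to 29 of the 30, 0 to 24 of the 24 and 0 to 6 of the 6 kept it, most without WTD replicate 3 or D7E replicate 3.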

Other observations

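The histone genes and single arrays described here were chosen after their values were seen, as were the idea about hypoxia and the step that left members of the fixed lists out of its test.

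Outside the lists that shifted as a whole, several matrix and growth factor genes changed in WTD against WTA in both directions. Timp1, an inhibitor of matrix proteases, was higher by log2 1.31 ± 0.18, Ccn2, a matricellular growth factor, by 1.48 ± 0.21, the basement membrane collagen Col4a2 by 1.17 ± 0.22, and Tgfb1 and Tgfb2 by 0.86 ± 0.17 and 0.82 ± 0.17 (SE; limma adjusted p = 0.00641 to 0.0436). Lower were Thbs2 at -1.84, Mfap4 at -1.27 and the protease Mmp3 at -0.93, so that 5 of 39 measured matrix and fibroblast markers were higher and 3 lower, and adjusted over the list alone 10 were higher and 10 lower. Among 38 myogenic regulators 3 were higher, Cdkn1c, the Notch target Hey1 (0.89 ± 0.17) and Msc, an antagonist of myogenic factors (1.03 ± 0.21), and 1 was lower, Myf6, a myogenic factor of mature muscle, which fell by 0.85 ± 0.18 (SE). Snrnp70, a component of the U1 spliceosomal particle, was higher by 1.04 and lipoprotein lipase Lpl by 0.92.

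Without WTD replicate 3, 80 probes differed between D7E and WTD, 35 higher and 45 lower in D7E, where 0 were higher with all arrays. Among the higher were Gpx7 (4.44), Pvalb (2.72), Rtl6 (1.9) and the glycolysis gene Tpi1 (1.34), for which WTD replicate 3 showed 0.115, 0.268, 0.432 and -0.154 of the shift of the other WTD arrays from D7E. Lower in D7E were the histone genes H2ac10 (-1.69), H2ac24 (-1.57) and H2ac15 (-1.56), closely related copies that a probe need not tell apart, and Mcm5 (-1.25) and Cenpa (-1.25); histone genes were not tested as a list. WTD replicate 3 showed -0.0555, 0.136 and 0.511 of the shift of the other WTD arrays from D7E for the 3 histone genes, 0.296 for Mcm5, 0.362 for Cenpa and a median of 0.384 over the 80 probes, so the H2ac10 and H2ac24 falls rest on WTD replicates 1 and 2. The 80 probes were picked on the shift of WTD replicates 1 and 2. A lower share in replicate 3 can therefore come in part from the picking. The mean of the proliferation list was -0.397 (camera adjusted p = 4.35e-07), that of slow fibre genes -0.365 and that of glycolysis genes 0.201 (adjusted p = 0.0178 and 0.0361), with adjusted p = 0.0719, 0.689 and 0.689 with an estimated correlation.

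D7E replicate 3 read apart from the other D7E arrays in several named genes, on the joint normalization of all 8 arrays. Cdkn1c read 8.13 there against 10.12 and 10.19 on the other D7E arrays and 8.32 and 8.03 in WTA, Pfkl 10.45 against 9.32 and 9.35, and Pvalb 12.38 against 11.17 and 11.07. Pabpn1 was highest on the same array, at 10.47.

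Pdk1, Egln3 and Pfkl, among the 12 largest falls in WTD against WTA, and Slc2a1 of the glycolysis list are known to be induced by hypoxia (in D7E against WTA Pdk1 passed, and Egln3, Pfkl and Slc2a1 did not, with adjusted p = 0.074, 0.153 and 0.189), and one hypothesis is that a wider set of such genes was lower in both WTD and D7E than in WTA. Of 31 other hypoxia-inducible genes, 5 were left out as members of the 23 lists (3 of them measured, Pgk1, Ldha and Ddit4), and of the remaining 26, 20 were measured, with 17 below 0 in each comparison against WTA and median log2 changes of -0.48 in WTD and -0.41 in D7E. Both shifts passed camera, with 0.000213 as the larger of both p-values, and with an estimated correlation the p-values were 0.0439 and 0.311; over all probes 4 genes, among them Ak4 (-1.20) and Kdm3a (-1.08), were lower in WTD and 0 in D7E, and adjusted over the list alone 9 and 3. D7E and WTD differed on this set by the same test, with a median of 0.25, 4 of 20 genes below 0 and camera p = 0.000238, but not with an estimated correlation (p = 0.218). One WTA array alone is argued against, since the highest median without one of them was -0.342, but both WTA cultures having less oxygen or more cells than the others may give the same values and stays open, as does an effect of PABPN1.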
